A study of Homo sapiens with 6 samples.

How the data were processed

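RNA was measured by sequencing in 6 samples of THP-1, a human monocytic leukaemia line grown in suspension in RPMI medium with 10% fetal bovine serum. Of these, 3 were left without exposure and 3 received 1 µM monensin for 16 h. Monensin is a polyether ionophore that carries sodium ions across membranes in exchange for protons. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with a directional NEBNext Ultra II kit, and single reads of 75 nt were sequenced on a NextSeq 500. The kit marks the strand of each RNA. The labels do not say whether RNA was selected by its poly(A) tail or by removing ribosomal RNA, and the strand setting used in counting is not given in the sources used here.

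The authors deposited raw HTSeq counts of reads per Ensembl gene for each library, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 038, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 1.22.2, with the human build hg38 (GRCh38); the annotation release is not given in the sources used here. Each count file holds 58395 genes and 5 tally lines for reads that were assigned to no gene. The tally lines were kept out of library sizes and tests. They made up 19.3% ± 0.388 of tallied alignments in untreated libraries and 21.6% ± 0.398 in monensin libraries (mean ± SD, n = 3). The authors also deposited a list of 2410 regulated genes with a log2 fold change for each, without standard errors or p-values. All of its absolute log2 fold changes were above 1.

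Gene counts summed to between 22975888 and 25710513 per library. Gene types, positions, exonic lengths and GC content were taken from GENCODE 29 on GRCh38, in which 58275 of the 58395 gene identifiers (99.79%) were found. Gene names are those in the deposited files, and older symbols of list members were matched through a gene name table. Of the 594 members of the gene lists, 593 were matched.

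Groups were taken from the treatment label of each sample. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, after its filter on low counts by group and TMM normalization, with treatment as the only term. This left 16542 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold change is an absolute log2 fold change of 1 or more. Standard errors of log2 fold changes were derived from the fitted coefficient and its F statistic. CPM values are counts scaled to TMM-adjusted library sizes and are given as mean ± SD of 3 libraries. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

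Before the data were examined, 25 gene lists, the tests, the alternatives and a rule for named genes were fixed. Each list was tested against all other tested genes with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. Camera with an estimated correlation and fry were run as alternatives. The rule named the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes with an average log2 CPM of at least 2, a symbol and no overlap between the groups. It also named up to 4 members per list with an average log2 CPM of at least 2 and the largest absolute change, and a set of anchor genes. Members that moved against the rest of their list are named where 5 or fewer did so; these, and LDHA, CD14, SLC7A1, NPM1, KRT8, MALAT1, NEAT1, MT-RNR1, MT-RNR2, POLRMT, TFAM, LONP1 and MT2A, were chosen after their values were seen. Some genes that the rule takes are not reported here.

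The alternatives fixed in advance were RLE size factors, total counts alone, no filter, a stricter filter (1 CPM in 3 libraries and 50 counts in all), the replicate number as a block, DESeq2 1.42.0, each library left out in turn, and an adjusted p under 0.01. A removal of GC content and length trends, and a fit without genes of the mitochondrial chromosome, were added after seeing the data. No pair of libraries was identical, and chi-square statistics per degree of freedom between replicates of a group ran from 1.93 to 5.09, so no library was counted as a repeat of another.

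The tests were tried on simulated counts with the library sizes and dispersions of the monensin against untreated comparison and 200 changed genes. Means were those of the untreated libraries. Over the 15838 simulated genes that passed its filter, edgeR recovered 59.2% of 49 genes changed 1.25-fold and 68% of 50 at 1.5-fold. It recovered 93.3% of 45 genes at 2-fold and 100% of 48 at 4-fold, with 11 false calls. DESeq2, over 16542 genes, recovered 80% of 50 genes at 2-fold with 8 false calls. Camera recovered 5 of 5 simulated lists of 25 genes raised 1.25-fold and called 0 of 20 unchanged lists, over 15828 genes. These simulated genes varied independently, unlike genes in cells. In the measured libraries 11208 of 16542 genes were called, against 200 changed in the simulation. The recovery rates and numbers of false calls therefore need not carry over.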

Results

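Transcript levels were measured by RNA sequencing in THP-1 cells, a monocytic leukaemia line, after 16 h with 1 µM monensin and in cells without exposure, with 3 libraries in each group. Gene counts came to 25710513, 24159573 and 25378060 in the untreated libraries and 24774546, 24170789 and 22975888 in the monensin libraries. Counts per gene were those the authors deposited. The comparison asks which transcripts differed after exposure to this sodium ionophore. The treatment label of the untreated samples reads no exposure and names no vehicle. Any effect of a vehicle therefore cannot be told apart from that of monensin.

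Monensin lowered all 13 messenger RNAs encoded by mitochondrial DNA and raised genes of the integrated stress response, the endoplasmic reticulum (ER) and the lysosome, while all 34 tested cell cycle genes fell. The mitochondrial gene MT-CO1, a subunit of cytochrome oxidase, went from 7026 ± 215 to 180 ± 19.1 CPM (mean ± SD, n = 3 per group). DDIT3, a transcription factor induced by ER and amino acid stress, rose from 12.2 ± 0.448 to 149 ± 8.28 CPM. GPNMB, a lysosomal and melanosomal glycoprotein, rose from 0.590 ± 0.0246 to 54.8 ± 7.55 CPM. The proliferation marker MKI67 fell from 617 ± 53.4 to 217 ± 5.59 CPM. By edgeR's quasi-likelihood test, 5638 of 16542 genes were raised and 5570 were lowered at an adjusted p under 0.05. Of these, 1556 were raised and 634 lowered at least 2-fold. The groups did not overlap for 71.11% of tested genes, against 10% by chance for 3 libraries against 3. The first principal component held 82.19% of the variance and separated the groups.

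Among called genes with an average log2 CPM of at least 2, a symbol and no overlap between the groups, the 12 with the highest log2 fold changes were TRPM8, KLHDC7B, GPNMB, INHBE, SDS, NUPR1, STC2, HES1, IL4I1, SLC6A9, C5AR1 and CHAC1. KLHDC7B rose by 8.61 on the log2 scale (SE 0.21, adjusted p = 1.99e-14). Its counts were 3, 1 and 0 in the untreated libraries and 602, 578 and 552 in the monensin libraries. The size of its rise is uncertain because the untreated counts are near 0. TRPM8, a cation channel, had 1 count over the untreated libraries and 585 over the monensin libraries, a ratio of 612 after scaling to depth with a 95% counting interval from 109 to 24200. NUPR1, a stress-induced chromatin protein, rose from 2.03 ± 0.261 to 85.4 ± 4.65 CPM. GPNMB lies on chromosome 7 from 23235967 to 23275108 on GRCh38, and KLHDC7B on chromosome 22 from 50545891 to 50551023. HES1, a transcriptional repressor downstream of Notch, rose from 0.845 ± 0.495 to 25.5 ± 0.402 CPM. C5AR1, the receptor for complement C5a, rose from 0.434 ± 0.191 to 9.56 ± 0.331 CPM.

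All 13 messenger RNAs of the mitochondrial genome fell, with a median log2 fold change of -4.42 (camera adjusted p = 6.83e-151, and adjusted p = 0.00798 with an estimated correlation). The changes ran from -3.21 to -5.29. MT-ND4, a complex I subunit, went from 9289 ± 479 to 322 ± 28.3 CPM, and MT-CO2 from 3388 ± 146 to 91.5 ± 9.29 CPM. Together these messenger RNAs held 4.19% ± 0.152 of gene counts in untreated and 0.197% ± 0.0178 in monensin libraries. The mitochondrial ribosomal RNAs did not follow them: MT-RNR1 went from 380 ± 15.1 to 906 ± 42.6 CPM (adjusted p = 2.22e-12) and MT-RNR2 fell by 0.29 on the log2 scale (SE 0.04, adjusted p = 2.58e-06). Counts at all 10 tested mitochondrial transfer RNA genes fell, among them MT-TT with a log2 fold change of -6.21 (SE 0.13). MT-TT, at 66 nt, is shorter than the 75 nt reads, and it starts at position 15888, right after MT-CYB ends at 15887. Its count is therefore uncertain as a measure of mature transfer RNA. Of the 12 most strongly lowered genes under the same limits, MTCO1P12 and MTND4P12 are pseudogene copies of mitochondrial genes, and their counts are uncertain because they share sequence with MT-CO1 and MT-ND4.

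**Figure D1:**
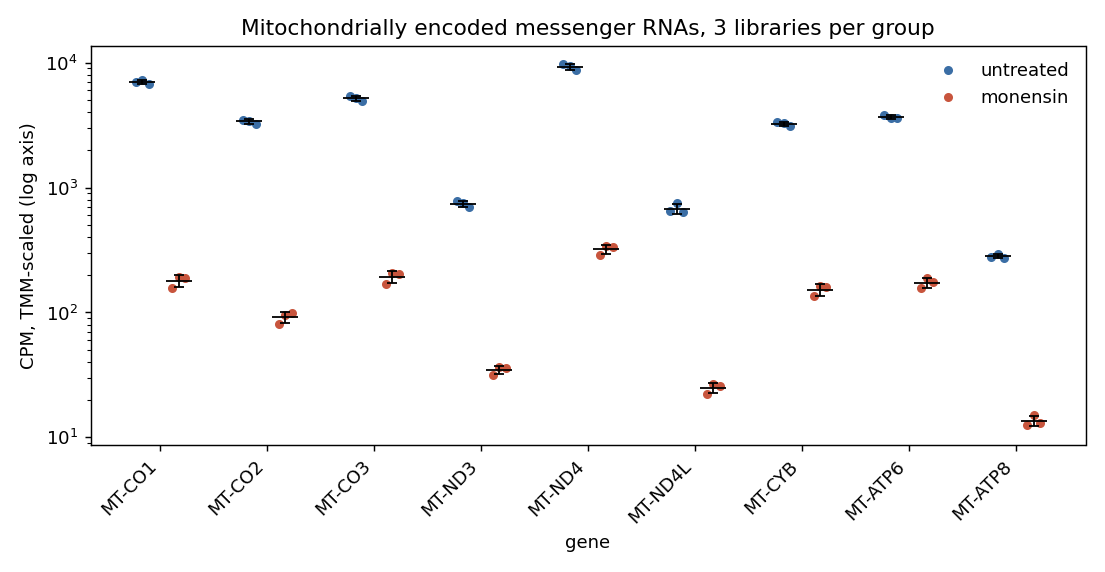
TMM-scaled CPM on a log axis for 9 mitochondrially encoded messenger RNAs in the 3 untreated (blue) and 3 monensin (red) libraries; points are libraries and black bars the mean ± SD. MT-CO1 fell from 7026 to 180 CPM, and no untreated library overlapped a monensin library for any gene shown.

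Of 29 tested nuclear genes of the respiratory chain, 18 fell and 2 rose, with a median log2 fold change of -0.17. Under total counts 11 fell and 8 rose, with a median of -0.09. With GC content and length trends removed 6 rose, and without untreated library 1 the list had 4 raised and 16 lowered. NDUFB5 and COX4I1 were the members that rose. SDHA, a subunit of succinate dehydrogenase, fell from 270 ± 1.80 to 152 ± 6.21 CPM, and NDUFS1, of complex I, from 152 ± 4.15 to 87.8 ± 3.12 CPM. The list was not called by camera (adjusted p = 0.0599, and adjusted p = 0.624 with an estimated correlation). It was called without untreated library 3 (adjusted p = 0.0279), without monensin library 3 (adjusted p = 0.0207), with DESeq2 (adjusted p = 0.00939), with no filter (adjusted p = 0.00278) and without mitochondrial genes (adjusted p = 0.0472).

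Of 34 genes of the ATF4 and integrated stress response, 33 rose and 0 fell, with a median log2 fold change of 1.63. SLC7A1 had a log2 fold change of 0.04 (SE 0.05) and was not called, except under total counts (adjusted p = 0.0405). The list was called by camera (adjusted p = 4.23e-75, and adjusted p = 0.000749 with an estimated correlation). STC2, a secreted glycoprotein, rose from 0.948 ± 0.132 to 28.8 ± 1.67 CPM, and CHAC1, which degrades glutathione, from 1.94 ± 0.345 to 33.0 ± 0.596 CPM. ATF4, the transcription factor after which the list is named, rose from 238 ± 5.99 to 806 ± 34.2 CPM, and TRIB3, a pseudokinase, from 54.1 ± 2.44 to 359 ± 15.4 CPM. ATF3, another stress-induced transcription factor, rose by 2.25 on the log2 scale (SE 0.21, adjusted p = 1.05e-07).

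Among ATF6 and XBP1 genes for ER folding and degradation, 23 of 24 rose and DERL1 fell, with a median of 0.56 (camera adjusted p = 3.2e-15, and adjusted p = 0.0307 with an estimated correlation). DERL1 had a log2 fold change of -0.17, and its call was lost under total counts (adjusted p = 0.0852); with GC content and length trends removed its log2 fold change was 0.00 (0.002). HERPUD1, which takes part in ER-associated degradation, rose from 64.3 ± 2.44 to 280 ± 4.17 CPM. The chaperone HSPA5 rose from 886 ± 13.2 to 1633 ± 19.3 CPM, and the transcription factor XBP1 from 155 ± 3.98 to 371 ± 8.22 CPM. Of 20 tested genes of the Golgi stress response, 16 rose and GLCE fell (3 fell with GC content and length trends removed), with a median of 0.71 (camera adjusted p = 5.23e-08, and adjusted p = 0.0348 with an estimated correlation). UAP1L1 rose from 71.9 ± 2.69 to 288 ± 8.48 CPM, RAB20 from 5.94 ± 0.922 to 21.8 ± 1.38 CPM and the Golgi matrix gene GOLGA2 from 51.1 ± 0.774 to 110 ± 3.61 CPM. Of 28 vesicle coat and cargo receptor genes of COPI and COPII transport, 19 rose and 4 fell (SEC23B, SEC24B, SAR1B and COPG2), with a median of 0.27. KDELR3, a receptor that returns proteins to the ER, rose by 1.15 on the log2 scale (SE 0.09), and COPG1, a coat subunit, by 0.79 (SE 0.04). Camera called this list (adjusted p = 0.00475), but not with an estimated correlation (adjusted p = 0.203). SAR1B lost its call with GC content and length trends removed (adjusted p = 0.689).

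Lysosomal and autophagy genes of the TFEB network rose in 34 of 37 tested members, and ATP6V1B2 fell. The median log2 fold change was 0.72 (camera adjusted p = 1.29e-23, and adjusted p = 0.00823 with an estimated correlation). NEU1, a lysosomal sialidase, rose from 68.0 ± 2.04 to 294 ± 5.35 CPM. SQSTM1, an autophagy receptor, rose from 112 ± 3.50 to 430 ± 16.1 CPM, and WIPI1, an autophagy protein, from 0.819 ± 0.121 to 7.76 ± 0.481 CPM. ATP6V1B2, a proton pump subunit, had a log2 fold change of -0.27 (SE 0.04), and its call was lost with GC content and length trends removed (adjusted p = 0.679).

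**Figure D2:**
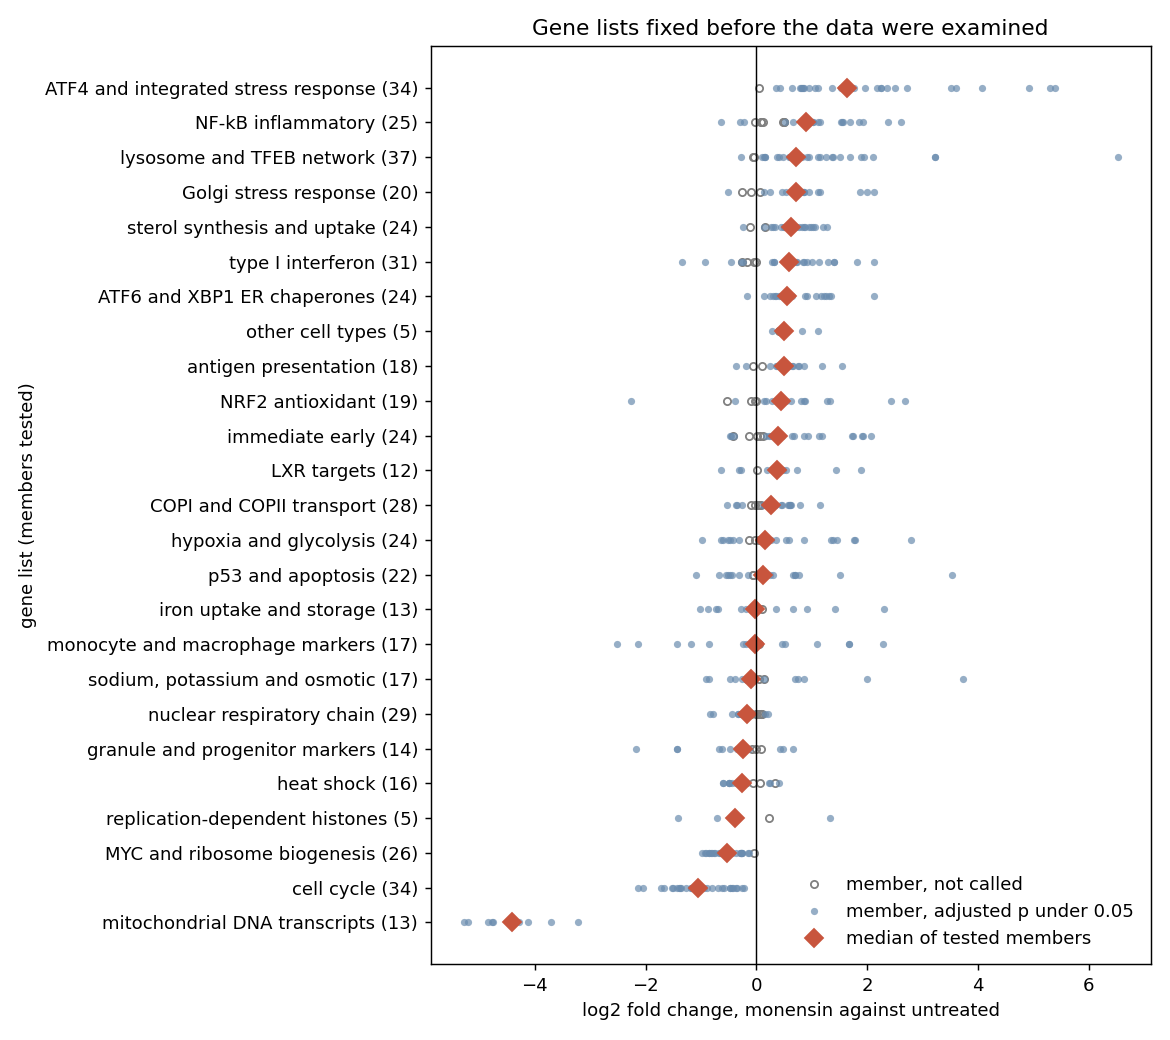
Log2 fold changes of the tested members of 25 gene lists (rows, with the number tested), monensin against untreated; filled circles are called members, open circles members not called, and red diamonds list medians. Medians ran from -4.42 for mitochondrial DNA transcripts to 1.63 for the ATF4 and integrated stress response list.

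Genes of sterol synthesis and uptake rose in 21 of 24 tested members and PMVK fell, with a median of 0.62; 2 fell without untreated library 3, without monensin library 3, with no filter or with GC content and length trends removed. MVD, an enzyme of the mevalonate pathway, rose from 48.3 ± 1.69 to 117 ± 5.28 CPM, and MSMO1 from 39.9 ± 2.69 to 91.3 ± 5.93 CPM. HMGCS1 rose by 0.76 on the log2 scale (SE 0.05) and INSIG1 by 0.86 (SE 0.06). Camera called the sterol list (adjusted p = 1.64e-09), which missed the threshold with an estimated correlation (adjusted p = 0.0528). Of 12 LXR target genes, 8 rose and 3 fell, with a median of 0.38 (0.19 with GC content and length trends removed), and the list was not called (camera adjusted p = 0.125, and adjusted p = 0.247 with an estimated correlation). APOE, an apolipoprotein, rose from 2.80 ± 0.191 to 10.3 ± 0.383 CPM, whereas the cholesterol exporter ABCA1 fell from 14.7 ± 2.17 to 9.41 ± 1.18 CPM; MYLIP and LPCAT3 also fell.

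**Figure D3:**
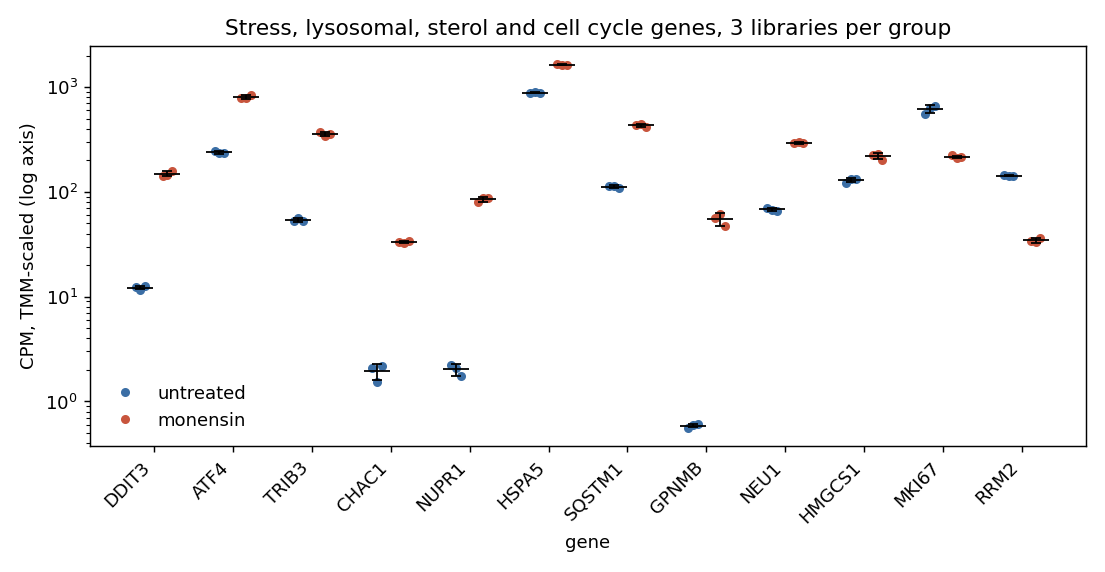
TMM-scaled CPM on a log axis for 12 named genes in the 3 untreated (blue) and 3 monensin (red) libraries; points are libraries and black bars the mean ± SD. DDIT3 rose from 12.2 to 149 CPM and RRM2 fell from 142 to 34.4 CPM.

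All 34 cell cycle genes fell, with a median log2 fold change of -1.04 (camera adjusted p = 3.7e-39, and adjusted p = 0.00798 with an estimated correlation). CCNE2, a G1/S cyclin, fell from 102 ± 5.13 to 23.2 ± 1.40 CPM, and RRM2, a subunit of ribonucleotide reductase, from 142 ± 1.53 to 34.4 ± 1.72 CPM. TYMS, thymidylate synthase, fell from 459 ± 12.7 to 144 ± 7.63 CPM. Among genes of MYC and ribosome biogenesis, 25 of 26 tested members fell, with a median of -0.53; NPM1, at -0.05 (SE 0.04), was not called. ODC1, an enzyme of polyamine synthesis, fell from 428 ± 2.69 to 216 ± 9.04 CPM, and POLR1A, the large subunit of RNA polymerase I, from 158 ± 14.1 to 84.0 ± 2.28 CPM. MYC itself had a log2 fold change of -0.14 (SE 0.04, adjusted p = 0.0110), and its call was lost under total counts (adjusted p = 0.286) and without monensin library 1 (adjusted p = 0.0654). Camera called the ribosome biogenesis list (adjusted p = 2.51e-09), but not with an estimated correlation (adjusted p = 0.161). Of 21 replication-dependent histone genes, 5 were tested; HIST2H2BE rose, HIST1H1C and HIST1H4C fell, the median was -0.39 (-0.72 with GC content and length trends removed), and the list was not called (camera adjusted p = 0.873). Histone counts are uncertain because many of the genes are near-identical copies. Their messages also lack poly(A) tails, and the way RNA was selected is not stated.

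Of 16 heat shock genes, 10 fell and 3 rose (HSPA1B, HSPB1 and BAG3), with a median of -0.27. The mitochondrial chaperonin HSPD1 fell from 1137 ± 17.1 to 748 ± 13.7 CPM, and HSP90AA1 from 2452 ± 99.2 to 1749 ± 57.2 CPM. HSPA1B shares sequence with HSPA1A, so its count is uncertain. With GC content and length trends removed, BAG3 lost its call (adjusted p = 0.717) and HSPB1 had a log2 fold change of -0.04 (adjusted p = 0.332). Camera called the heat shock list (adjusted p = 0.0447), but not with an estimated correlation (adjusted p = 0.516), under total counts (adjusted p = 0.0858), under the stricter filter (adjusted p = 0.0800), or without untreated library 1 (adjusted p = 0.0593), untreated library 2 (adjusted p = 0.0548), monensin library 1 (adjusted p = 0.0575) or monensin library 2 (adjusted p = 0.0603). Of 22 genes of p53 and apoptosis, 11 rose and 8 fell, with a median of 0.12 and no call (camera adjusted p = 0.368, and adjusted p = 0.440 with an estimated correlation). The median was 0.21 under total counts and 0.04 with GC content and length trends removed. BBC3, a pro-apoptotic BH3-only gene, rose from 7.45 ± 0.431 to 21.1 ± 0.159 CPM, CDKN1A, a cyclin-dependent kinase inhibitor, by 0.78 on the log2 scale (SE 0.07) and the death receptor gene TNFRSF10B by 0.70 (SE 0.05).

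Inflammatory genes of the NF-kB list rose in 15 of 25 tested members and fell in 3 (NFKB1, NLRP3 and SOD2), with a median of 0.90. ICAM1, an adhesion molecule, rose from 3.96 ± 0.645 to 24.4 ± 0.798 CPM, TNFAIP3, a feedback inhibitor, from 6.09 ± 0.438 to 21.9 ± 2.67 CPM, and the cytokine TNF from 8.76 ± 0.655 to 16.3 ± 1.15 CPM. CXCL8 had 1.30 ± 0.0516 and 1.28 ± 0.107 CPM in the untreated and monensin groups (adjusted p = 0.937). IL1B had 1.45 ± 0.138 and 2.01 ± 0.722 CPM (adjusted p = 0.0886), and it was called without monensin library 2 (adjusted p = 0.0488) or monensin library 3 (adjusted p = 0.0367). Camera called the NF-kB list (adjusted p = 1.62e-05), but not with an estimated correlation (adjusted p = 0.124).

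Of 31 interferon-stimulated genes, 22 rose and 5 fell, among them MX2, OAS3, CMPK2 and TRIM22, with a median of 0.59. STAT2, a signal transducer of interferon receptors, rose from 20.3 ± 1.98 to 72.1 ± 1.57 CPM, and IRF7 from 3.85 ± 0.347 to 10.3 ± 0.884 CPM. The list was called by camera (adjusted p = 0.0213) and not with an estimated correlation (adjusted p = 0.123). OAS3 lost its call under total counts (adjusted p = 0.0652) and without untreated library 2 (adjusted p = 0.0648). Of 18 antigen presentation genes, 14 rose and TAP2 and PSMB8 fell, with a median of 0.50 (camera adjusted p = 0.000276, and adjusted p = 0.243 with an estimated correlation). HLA-DMA rose from 4.88 ± 0.267 to 11.2 ± 1.08 CPM, and CD74, the invariant chain of MHC class II, from 174 ± 1.11 to 296 ± 19.1 CPM. Counts of HLA genes are uncertain because of near-identical copies. PSMB8 lost its call under total counts (adjusted p = 0.0560). Immediate early genes rose in 16 of 24 members and fell in 3 (FOSL1, EGR1 and MCL1), with a median of 0.39; DUSP4, a MAP kinase phosphatase, rose from 10.1 ± 0.568 to 37.9 ± 4.94 CPM. This list was called by camera (adjusted p = 0.00528) and not with an estimated correlation (adjusted p = 0.0894).

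Of 24 genes of hypoxia and glycolysis, 13 rose and 7 fell, with a median of 0.16 (0.25 under total counts). The angiogenic factor VEGFA rose from 35.1 ± 1.49 to 243 ± 17.3 CPM and PFKFB4, a regulator of glycolysis, from 10.9 ± 0.716 to 37.3 ± 2.00 CPM, whereas the lactate dehydrogenase gene LDHA fell from 1129 to 571 CPM (log2 fold change -0.98, SE 0.04). The list was called by camera (adjusted p = 0.0398), but not with an estimated correlation (adjusted p = 0.151), with DESeq2 (adjusted p = 0.102), without untreated library 1 (adjusted p = 0.0593) or without untreated library 3 (adjusted p = 0.0658). Of 13 iron genes, 5 rose and 6 fell. Both ferritin genes rose, FTL from 1910 ± 145 to 5117 ± 81.8 CPM and FTH1 from 92.0 ± 2.53 to 452 ± 18.1 CPM, with FTH1 uncertain because of its pseudogene copies; SLC11A2, SLC39A14 and SLC25A37 also rose. The iron exporter SLC40A1 fell from 14.1 ± 0.980 to 6.92 ± 0.403 CPM. TFRC, the transferrin receptor, had 388 ± 24.6 and 380 ± 26.4 CPM in the untreated and monensin groups (adjusted p = 0.665), and a log2 fold change of 0.20 (adjusted p = 0.000316) with GC content and length trends removed. The median of the iron list was -0.03, while its mean was 0.15 and its test pointed upward without a call (camera adjusted p = 0.154, and adjusted p = 0.516 with an estimated correlation); the median was 0.06 under total counts, and the list was called with DESeq2 (adjusted p = 0.0487). Without monensin library 3 the median was 0.026, and without untreated library 1 or 3 or monensin library 1 or 2 it was -0.085, -0.004, -0.07 and -0.048.

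Of 19 NRF2 antioxidant genes, 13 rose and GCLM and AKR1C2 fell, with a median of 0.44. HMOX1, heme oxygenase 1, rose by 2.69 on the log2 scale (SE 0.21) and OSGIN1 by 2.44 (SE 0.14), while AKR1C2 went from 28.9 ± 4.12 to 5.97 ± 0.720 CPM and is uncertain because of its close paralogs. GCLM lost its call with GC content and length trends removed (adjusted p = 0.118). Camera called the list (adjusted p = 0.0291), but not with an estimated correlation (adjusted p = 0.407) or without untreated library 3 (adjusted p = 0.0556). Of 17 sodium, potassium and osmotic genes, 6 rose and 8 fell; the median was -0.09, the mean 0.29 and the upward test gave no call (camera adjusted p = 0.696). Under total counts 7 rose and 4 fell, with a median of -0.003. The 2 members raised at least 2-fold had an average log2 CPM under 2 and are not named. SLC38A2, an amino acid transporter, rose by 0.87 on the log2 scale (SE 0.06). The inositol transporter SLC5A3 and the sodium, potassium and chloride cotransporter SLC12A2 had log2 fold changes of -0.91 (SE 0.09) and -0.85 (SE 0.08).

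Of 17 tested monocyte and macrophage markers, 6 rose and 7 fell, with a median of -0.03 and no call (camera adjusted p = 0.107, and adjusted p = 0.239 with an estimated correlation). The sign of this median was not stable: it was 0.05 under total counts, 0.025 with GC content and length trends removed, and 0.04 without untreated library 3. It was -0.096 without untreated library 2, -0.074 without untreated library 1 and -0.004 without monensin library 1. S100A8 and S100A9, which form calprotectin, fell by 2.52 (SE 0.08) and by 2.14 (SE 0.07) on the log2 scale. LYZ, lysozyme, fell from 791 ± 14.3 to 292 ± 24.2 CPM, while the integrin ITGAX rose from 37.0 ± 4.63 to 117 ± 6.65 CPM. CD14 rose by 2.30 on the log2 scale (SE 0.23) but at a low level, from 0.48 ± 0.069 to 2.37 ± 0.289 CPM. Of 14 tested granule and progenitor markers, 8 fell and 3 rose (AZU1, CEBPE and CFD), with a median of -0.24 (camera adjusted p = 0.0835, and adjusted p = 0.314 with an estimated correlation). SERPINB10 fell from 11.5 ± 0.408 to 2.55 ± 0.244 CPM and MS4A3 from 55.1 ± 1.93 to 20.5 ± 0.337 CPM. That list was called with no filter (median -0.37, adjusted p = 0.0107) and with GC content and length trends removed (adjusted p = 0.0165). Its median was -0.15 under total counts, -0.11 under the stricter filter and -0.37 with DESeq2. CEBPE lost its call with DESeq2 (adjusted p = 0.152), with the trends removed (adjusted p = 0.226), and without untreated library 2 (adjusted p = 0.0512), untreated library 3 (adjusted p = 0.05) or monensin library 3 (adjusted p = 0.0651). Of 24 markers of other cell types, 5 passed the filter; 4 rose, among them NKG7, PECAM1 and COL1A1, and KRT8, at 0.42 (SE 0.34), was not called. NKG7, a cytotoxic granule gene, rose from 12.9 ± 1.45 to 28.1 ± 0.878 CPM, and the adhesion molecule PECAM1 from 262 ± 3.81 to 316 ± 11.2 CPM. COL1A1 lost its call with DESeq2 (adjusted p = 0.121) and without untreated library 2 (adjusted p = 0.0891) or monensin library 2 (adjusted p = 0.0614). In each of these settings 2 members of the list rose. The list was not called (median 0.50, and 0.30 with trends removed; camera adjusted p = 0.129, and adjusted p = 0.293 with an estimated correlation).

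In all, 16 of the 25 lists were called by camera at the preset correlation and 6 with an estimated correlation: mitochondrial DNA transcripts, ATF4 and integrated stress response, ATF6 and XBP1 ER chaperones, Golgi stress response, lysosome and TFEB network, and cell cycle. Member counts adjusted over the list alone equalled those over all genes tested in 22 lists. Adjusted over the list alone, the iron list had 6 raised and 6 lowered, the sodium, potassium and osmotic list 6 raised and 9 lowered, and the immediate early list 16 raised and 4 lowered.

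Long non-coding genes rose more often than they fell. Among 725 tested lincRNA genes 353 rose and 50 fell (median 0.45), and among 882 antisense genes 353 rose and 81 fell (median 0.38). By contrast, 4310 of 12826 protein-coding genes rose and 5047 fell (median -0.03). Coding genes matched on expression to long non-coding genes of all kinds had a median of 0.27. The nuclear RNA MALAT1 went from 730 ± 185 to 2438 ± 169 CPM and NEAT1, the scaffold of paraspeckles, from 87.5 ± 14.3 to 455 ± 9.54 CPM. The share of tallied alignments that HTSeq assigned to no feature was 8.80% ± 0.191 in untreated and 10.9% ± 0.441 in monensin libraries. The feature setting of the counting is not given, so this share may hold reads from introns of annotated genes. Counts of antisense genes are uncertain because the strand setting of the counting is not given.

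The authors' deposited table lists 2410 genes, 1688 with a positive and 722 with a negative log2 fold change. Of these, 2071 were tested here, and all 2071 were called in the direction of the authors' deposited table (85.93% of the list); the other 339 did not pass the count filter. Across the 2071 genes, which are not independent replicates, fold changes from the same counts had a Pearson correlation of 0.9997 with those in the authors' deposited table and a median absolute difference of 0.0192. Of 2190 genes called at least 2-fold here, 2037 were in that table and 153 were not.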

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

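The comparison of non-coding genes near and away from coding genes was chosen after the results were seen, and the removal of GC content and length trends was added after seeing the data, though before its result for these genes was seen. The share of alignments that fell in no annotated gene, which no comparison uses, was higher in each monensin library than in any untreated library. Its mean was 10.89% ± 0.441 with monensin and 8.80% ± 0.191 without (SD, n = 3 per group; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Among the 41853 genes that were not tested, 259 had counts in all 3 monensin libraries and in no untreated library, and 82 the reverse.

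Long non-coding genes of all annotated kinds rose more often than they fell: 868 of 1977 were raised and 161 lowered, with a median log2 fold change of 0.40. Coding genes matched on expression had a median of 0.27 (1000 draws, 95% range 0.23 to 0.32), so low expression may account for much of the shift. The difference from coding genes was 0.44 before matching and 0.131 after. The excess of 0.131 over the margin of 0.1 set in advance is smaller than the spread of the draws, which keeps this open. The 614 genes with a coding gene on their strand overlapping them or within 10 kb upstream had a median of 0.375. The other 1363 had 0.41 (612 raised, 105 lowered), 0.135 above matched coding genes (95% range of draws 0.22 to 0.33). This test was fixed in advance and left read-through undecided, because 0.135 exceeds the margin of 0.1 by less than the spread of the draws. The difference between near and away genes, matched on expression, was -0.034 (bootstrap 95% range -0.128 to 0.055), and at 100 kb it was 0.053 (-0.015 to 0.096). Both ranges end below 0.1, at 100 kb only just, a margin applied here after the results were seen. These near and away values argue against read-through on the same strand as the whole cause and leave a smaller part open. Coding genes on the opposite strand were not considered. Because the strand setting of the counting is not given, reads from that strand cannot be excluded. Coding genes were taken as near whether or not they were expressed. Removing trends with GC content and length left a difference of 0.362 between non-coding and coding medians (bootstrap 95% range 0.32 to 0.40; 0.44 before), which argues against those trends as the whole cause. An effect of monensin on non-coding transcripts stays among the open explanations.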

How the results depend on the processing

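The removal of GC content and length trends and the fit without mitochondrial genes were chosen after seeing the data. Counts of raised and lowered genes, in all and at least 2-fold, stayed within 1.5 times the reported counts under each alternative. The genes behind these counts changed more. Of the 11208 genes called, 9487 were called in the same direction with GC content and length trends removed, 9543 with DESeq2 and 11105 under RLE size factors. Across coding genes, GC content and log2 fold change had a Spearman correlation of 0.32. Raised genes ran from 5211 to 5493 and lowered genes from 5260 to 5484 with 1 library left out. DESeq2 gave 4598 and 5238, and total counts alone 6582 and 4605, with a shift of 0.086 in the median log2 fold change. The share of the authors' genes called the same way was 67.8% under the stricter filter and 100% with no filter, which test fewer and more genes. Over 399 alternatives of the 25 lists, 362 kept direction and side of the threshold, 21 lost the call, 16 gained it and 0 reversed. Over 2451 alternatives of 176 named genes the numbers were 2404, 32, 3 and 12. For the changes below, the cause was not tested. With an estimated correlation, calls were lost at unchanged medians for sterol (0.625), COPI and COPII (0.266), hypoxia (0.164), NRF2 (0.439), immediate early (0.393), NF-kB (0.898), interferon (0.594), antigen presentation (0.496), heat shock (-0.266) and ribosome biogenesis (-0.525). Fry, which does not compare a list with other genes, added LXR (0.378), iron (-0.028), sodium and potassium (-0.089), p53 (0.125), nuclear respiratory chain (-0.175), monocyte (-0.032), granule (-0.239) and other cell types (0.503). Heat shock lost its call under total counts (median -0.18), the stricter filter (-0.248) and without untreated library 1 or 2 or monensin library 1 or 2 (range over left-out libraries -0.298 to -0.256). Hypoxia lost it with DESeq2 (0.135) and without untreated library 1 or 3 (range 0.141 to 0.189), and NRF2 without untreated library 3 (range 0.391 to 0.452). The nuclear respiratory chain gained a call with no filter (-0.197), DESeq2 (-0.204), mitochondrial genes left out (-0.176) and without untreated library 3 or monensin library 3 (range -0.21 to -0.146). The granule list gained it with no filter (-0.367) and with trends removed (-0.282), and iron with DESeq2 (-0.057). CXCL8 reversed its log2 fold change under total counts (0.065), with trends removed (0.028) and without monensin library 2 (range -0.093 to 0.02). TFRC reversed under total counts (0.059), with trends removed (0.198) and without monensin library 3 (range -0.085 to 0.026). NPM1 reversed under total counts (0.035) and trend removal (0.085), SLC7A1 under trend removal (-0.009) and without untreated library 1 (range -0.011 to 0.081), and DERL1 (0.002) and HSPB1 (-0.041) under trend removal. Of these 6 genes, DERL1 and HSPB1 were called in the reported test. The samples share only replicate numbers: deviations of same-numbered libraries correlated at -0.381, 0.281 and -0.125, and not every library correlated best with its own number. With the replicate block, 5515 genes were raised and 5435 lowered, and the heat shock list (median -0.266, adjusted p = 0.0743) missed the threshold. At 22975888 gene counts or more per library, a count of 0 allows 3 counts, or at most 0.131 CPM.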

Other observations

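The gene families, the tests of mitochondrial RNAs and the comparison of replication with mitosis genes were chosen after the results were seen. The families came from 19 patterns of gene symbols that were looked at, of which 18 had at least 3 tested coding genes. Camera at the preset correlation called 10 of them and, with an estimated correlation, 0, so they are described as counts of genes called by edgeR. Cytosolic ribosomal protein genes rose in 70 of 79 members and fell in 7 (median log2 fold change 0.40, and 0.49 under total counts; adjusted p = 0.602 with an estimated correlation). Mitochondrial ribosomal protein genes had 59 of 78 members lowered and 2 raised (median -0.28, camera adjusted p = 0.602 with an estimated correlation). Under total counts 49 were lowered and 6 raised, with a median of -0.20. Of 38 genes for mitochondrial DNA and RNA metabolism, 31 fell and 3 rose (median -0.41, and -0.32 under total counts; adjusted p = 0.208 with an estimated correlation). TFAM, which packages mitochondrial DNA, fell from 104 ± 4.37 to 54.7 ± 3.03 CPM, and POLRMT, the mitochondrial RNA polymerase, from 92.7 ± 1.53 to 77.5 ± 3.73 CPM, while the protease LONP1 rose from 217 ± 2.57 to 380 ± 6.07 CPM (mean ± SD, n = 3 per group; edgeR). All 5 tested metallothionein genes rose, among them MT2A by 1.95 on the log2 scale (SE 0.12). Of 37 proteasome subunit genes 27 fell and 2 rose (20 and 4 under total counts, where the median was -0.12 against -0.20), of 8 chaperonin CCT genes 7 fell and 1 rose, and of 14 cathepsin genes 12 rose and 1 fell. The other patterns with a camera call were ATP6 genes (15 of 22 raised, 2 lowered), the PSMD subset of the proteasome (11 of 14 lowered, 1 raised) and mTORC1 regulators (10 of 16 raised, 3 lowered).

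All 13 mitochondrial messenger RNAs fell, with a median log2 fold change of -4.42. The mitochondrial ribosomal RNAs did not follow them and moved apart, with log2 fold changes of 1.255 for MT-RNR1 and -0.286 for MT-RNR2. These values argue against a loss of whole mitochondria only if ribosomal RNA was captured alike in both groups. That is not known, because the way RNA was selected is not stated. Reads moving to nuclear copies would raise the annotated nuclear pseudogenes of mitochondrial genes, but all 11 tested fell, with a median of -4.569. A selection of RNA by poly(A) tails that had become shorter cannot be told apart from lower RNA levels: the way RNA was selected is not stated, only 5 of 21 histone genes whose messages lack tails passed the filter, and transfer RNA genes fell with a median of -3.047, which either could give. Lower transcription and faster decay of mitochondrial RNA stay open as hypotheses, and counts at 1 time do not separate them.

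Across the 12 messenger RNAs of the heavy strand, which are not independent replicates, gene position and log2 fold change had a Spearman correlation of -0.17 (permutation test, two-sided p = 0.589).

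With GC content and length trends removed, which was added after seeing the data but before this result was seen, all 34 cell cycle genes were still lowered, with a median of -1.047 (bootstrap 95% range -1.25 to -0.66), which argues against the trends as the whole cause. The 17 replication genes of the list had a median of -1.18 and the 17 mitosis genes -0.58, a difference of -0.599 (permutation test over genes, two-sided p = 0.002, 100000 permutations), and -0.83 with the trends removed. Fewer cells in S phase may give this pattern; it is a hypothesis, genes of a list are not independent, and cell numbers per phase were not measured.

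The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. Each split other than the real one has libraries of both groups on both sides. Most of the treatment difference then adds to the spread within sides, which works against gene calls, and a part stays between sides. The counts from these splits are therefore not a chance reference, for genes or for lists. By edgeR the real split gave 5638 raised and 5570 lowered genes, and 1556 and 634 at least 2-fold; for each count, 1 of the 10 splits, the real one, reached it. The highest of the other splits was 0 for each, with 133 genes at an unadjusted p under 0.05 against 11604 in the real split. For lists called by camera at the preset correlation, 2 of the 10 splits reached the real count of 16, since the highest of the other splits also gave 16 and the lowest 9. With an estimated correlation the real split called 6 lists and the highest of the other splits 0.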
